A study of Mus musculus with 2 samples.

How the data were processed

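The series holds sgRNA sequencing of genomic DNA from MIN6 cells that a sort divided by proinsulin staining, with 1 library for the high and 1 for the low population. Per the labels and the series' design text, the guide region was amplified by PCR and made into Truseq libraries, and Bowtie2 is named in the submitters' processing notes with no version. The deposited table gives read counts per guide for both libraries, not normalized, per the file headers. No genome build is named and guide sequences were not used here, so cut sites, exons and coordinates are not given. Gene names are those of the deposited table, and the results of some single genes are not reported here.

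The table as received had no separators between its fields, so the 2 counts of a guide formed 1 string of digits, and the analysis planned for separate counts was applied to counts recovered from these strings, a departure from the plan. A guide absent from 1 library carried NA there and was given 0, and the 2561 guides absent from proinsulin-high carried no gene name and were left unnamed. Strings of 2, 4 or 6 digits were split in the middle. None of the 81617 strings of 4 digits had a 0 in position 3, against 10.3% with a 0 in the last position, which limits other splits to 0.0357%. For the 3505 strings of 6 digits the same limit was 0.824%. An odd-length string was read where zeros forced the split, or where exactly 1 reading lay within 8-fold of the centre of the log2 ratios, −0.46. This left 975 guides (0.772%) unread. The 8-fold limit was set after the strings had been seen, among them those of Ins1, Ins2, Pcsk1, Pcsk2 and Pdx1, and before gene scores were computed. It gives more calls than a 32-fold limit, settled strings alone or the least favourable readings, whose counts stand beside the main ones, and a 4-fold limit gave 18 calls toward high and 4 toward low. Of 192 strings of 3 digits past the count filter whose split was forced, 11 (5.73%, exact 95% interval 2.89 to 10.0) lay beyond 8-fold. If such cases were all misread among the 2444 strings of 3 digits used with several readings, about 140 guides would be wrong, and these would be the guides with the strongest ratios. For the 7706 strings of 5 digits used with several readings, only 36 forced splits were at hand, 0 of them beyond 8-fold, too few to set a close limit.

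Of 126372 guides listed, 90350 had at least 30 reads summed over both libraries and were kept, 79967 of them split in the middle and 10151 (11.2%) read from odd-length strings with several readings. Log2 ratios of proinsulin-high over proinsulin-low were computed with a pseudocount of 1 read after scaling to total reads and centred on the median guide. They were turned into z scores within 20 bins of read number. Genes with at least 3 guides were scored in each direction by robust rank aggregation with an alpha of 0.25, written in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Each gene's p came from 1000000 sets of uniform random ranks, with as many ranks per set as the gene had guides (smallest p 1e-06). It is called a permutation p below, although no guides were permuted. Benjamini-Hochberg adjustment ran over 19416 genes with a threshold of 0.05. These p-values are 1-sided in each direction and compare guides within 2 libraries, so they say nothing about a second sort. The 2372 genes with fewer guides were not tested.

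The genes named were the 12 with the lowest score in each direction among those with at least 4 guides, 22 genes of insulin synthesis, folding and beta cell identity, and the highest and lowest member of each of 19 gene lists. Called genes outside this rule, and list members named because they passed when adjusted over the list alone, were chosen after their values were seen. The rule, the lists, the tests and the main alternatives were fixed before the data were examined, and alternatives on the reading of strings and on guides per gene were added after the data had been seen. Alternatives covered the count filter, pseudocount, scaling, guide score, gene statistic, reference ranks, threshold and each of the 2 parts of the guide library.

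The procedure was tested on simulated data for the comparison of the 2 libraries, with 200 genes changed in all their guides, and counts joined and read back. Among 19300 genes tested, 11 of 34 genes were called at 2-fold toward proinsulin-high and 14 of 34 toward proinsulin-low. At 4-fold 30 of 32 and 29 of 29 were called. At 8-fold, where many strings could not be read, 20 of 21 and 7 of 15 were called of the genes still testable, against 33 of 33 in each direction with counts kept apart. Of 19135 unchanged genes 3 were called. Misread strings made up 0.0502% of guides past the filter and 6.35% of those against changed genes. The simulated 8-fold genes toward proinsulin-low had a median log2 ratio of 0.092 after reading, where −3.00 was put in.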

Results

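MIN6, a mouse insulinoma line that makes and secretes insulin, carried a pooled CRISPR knockout library (GeCKOv2) in which each guide RNA directs Cas9 to 1 gene. Cells were stained for proinsulin, the precursor, and for insulin, the product, and were sorted into a proinsulin-high and a proinsulin-low population. Guide sequences amplified from the genomic DNA of each population were counted, so a guide found more often in 1 population marks a gene whose loss went with that staining. There was 1 library per population and no replicate. The proinsulin-high library held 3784046 reads (median 22 per guide) and the proinsulin-low library 5431557 reads (median 32 per guide) over the 125397 guides whose counts could be read. Intervals given here cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

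The first question was which gene losses gathered in the proinsulin-high population. Guides against Pcsk1, the endoprotease that starts the conversion of proinsulin to insulin, had a median log2 ratio of 2.01, a 4.03-fold excess in proinsulin-high, with 3 of 4 guides higher. Guides against Heatr3, a ribosome assembly factor, had a median log2 ratio of 1.35 with 5 of 5 guides higher. Depdc5, a subunit of the GATOR1 brake on mTORC1, reached 1.34 with 5 of 5 guides higher, and the transporter-like protein Slc38a10 reached 1.21 with 6 of 6. Hid1, a Golgi protein needed for dense core granule formation, had 1.11 with 4 of 4 guides higher.

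In all, 18 of 19416 genes were called toward proinsulin-high at an adjusted p of 0.05 by robust rank aggregation of guides, with medians from 0.63 to 2.01 and every guide on the called side for 11 of them. Bccip (1.95, 4 of 5 guides), Dkc1 (1.32, 4 of 4), Mdn1 (1.18, 4 of 5) and Wdr36 (0.99, 4 of 5) have known roles in ribosome assembly. Bccip, Mdn1 and Wdr36 were tested but not called with settled strings alone, with a 32-fold reading limit or with the least favourable readings, and Dkc1 was not called with no count filter or with raw ratio ranks. Sugt1, a cochaperone, had 1.33 with 6 of 6 guides higher. The kinase Gsk3b had 1.22 with 4 of 4, and Prkar1a, the regulatory subunit of protein kinase A, had 1.43 with 3 of 4. The other 6 called genes fell outside the naming rule and were named after their values were seen. They were Dpagt1 (1.62), the first enzyme of N-glycan assembly, the cohesin subunit Smc3 (1.47), Paxip1 (1.40), the transcription factor Sp1 (1.23), the aminoacyl-tRNA ligase Eprs (0.68) and the olfactory receptor Olfr1475 (0.63). Dpagt1 and Paxip1 had 3 guides each, and Paxip1 could not be tested with settled strings alone. Olfr1475 had only 2 of 4 guides higher, and its median turned to −0.12 with a count filter of 10. Smc3 was not called with that filter, with none or with medians of z scores. Sp1 and Eprs were tested but not called with settled strings alone, a 32-fold reading limit, raw ratio ranks or medians of z scores. Eprs was also lost with a count filter of 10 and without its most extreme guide. Hid1 and Gsk3b were not called with medians of z scores, nor Paxip1, Sugt1, Mdn1 and Wdr36 with raw ratio ranks. Prkar1a was not called with the least favourable readings. Prkar1a, Mdn1 and Wdr36 were not called without their most extreme guide. The test compared guides within these 2 libraries, not the populations, and the difference has no replicate check. The call count was 9 with settled strings alone, 11 with a 32-fold reading limit, 13 with the least favourable reading of each string, 4 with a count filter of 100, 11 without each gene's most extreme guide and 115 with ranks among non-targeting guides, and Pcsk1, left with fewer than 3 guides, could not be tested under the first 2 of these or with the filter of 100. Of the calls lost, 3 with settled strings, 1 with the 32-fold limit, 15 with the filter of 100 and 2 without the most extreme guide were of genes left with too few guides to test.

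**Figure D1:**
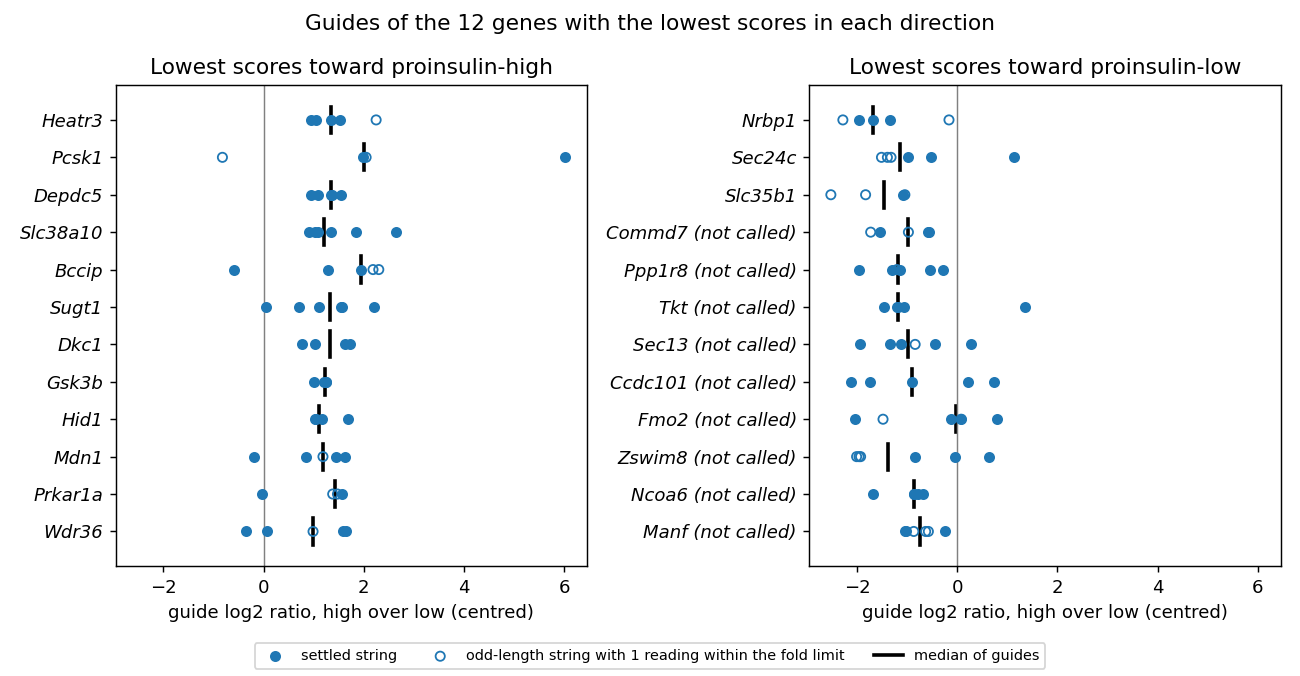
Each point is the centred log2 ratio (proinsulin-high over proinsulin-low) of 1 guide, for the 12 genes with the lowest rank aggregation scores in each direction, and bars mark the gene medians. Filled points come from strings whose split was settled and open points from odd-length strings with 1 reading within the fold limit; Heatr3 guides all lie above 0 and Nrbp1 guides all lie below 0, while 1 guide of Pcsk1 lies at −0.82.

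Toward proinsulin-low, 3 of the 6 called genes act in transport from the ER to the Golgi. Guides against Sec24c, a cargo-binding subunit of the COPII coat, had a median log2 ratio of −1.15 with 5 of 6 guides lower. Sec22b, a SNARE of ER to Golgi vesicles, had −1.49 and Yipf5, a membrane protein of the same step, had −2.28, each with 3 of 3 guides lower. Nrbp1, a pseudokinase, had −1.69 with 5 of 5 guides lower. Slc35b1, which carries ATP into the ER, had −1.46 with 4 of 4. It was not called with a count filter of 10, with none or with medians of z scores. Sumo2 had −1.96 with 3 of 3, but was not called with no filter, with medians of z scores or with the least favourable readings. Sec24c was tested but not called with settled strings alone, a 32-fold reading limit, the least favourable readings or raw ratio ranks.

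These were the 6 genes called toward proinsulin-low, and Sec22b, Yipf5 and Sumo2, with 3 guides each, lay outside the naming rule and were named after their values were seen. The other 9 genes with the lowest scores were not called. Among them were Commd7 (−0.97, permutation adjusted p = 0.0655), Ppp1r8 (−1.18, permutation adjusted p = 0.0655), the transketolase Tkt (−1.18, permutation adjusted p = 0.0777) and the COPII cage protein Sec13 (−0.98, permutation adjusted p = 0.0913). The ER protein Manf had −0.75 with 6 of 6 guides lower (permutation adjusted p = 0.178), and Ccdc101 (−0.90), Zswim8 (−1.39), Ncoa6 (−0.86) and Fmo2 (−0.02) also missed the threshold. The call count was 1 with settled strings alone (Nrbp1, with 4 of the 5 others not testable), 1 with the least favourable readings (Sec22b), 3 with a 32-fold limit (Sec22b, Yipf5 and Nrbp1, with 2 of the 3 others not testable) and 4 with a 4-fold limit, where Slc35b1, Sumo2 and Yipf5 were not testable. It was 1 with a count filter of 100, 3 without the most extreme guide and 3 with at least 4 guides per gene, where all the genes lost were not testable, and 35 with ranks among non-targeting guides.

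The next question was how genes with a known place in insulin synthesis behaved. For Pcsk1, 73 reads were counted in proinsulin-high and 26 in proinsulin-low for a guide whose string was settled, a share of 73.7% in proinsulin-high (exact 95% interval 63.9 to 82.1). A second Pcsk1 guide had 53 reads in proinsulin-high and was absent from proinsulin-low, where a count of 0 allows up to 3 reads. Another was read as 165 against 57, although 16 against 557 was also possible, and the last as 9 against 24, although 92 against 4 was also possible, and 2 of the 6 Pcsk1 guides were unread. Cpe, the carboxypeptidase that trims proinsulin after cleavage, had a median of 1.43 with 3 of 3 guides higher but was not called (permutation adjusted p = 0.147), and 2 of its 5 guides were unread. Pcsk2, the second convertase, had −0.13 with 4 of 5 guides lower (permutation adjusted p = 0.997), and its chaperone Scg5 had −0.46 with 4 of 4 lower (permutation adjusted p = 0.897).

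Ins2, the main insulin gene in mouse beta cells, had a median log2 ratio of −0.33 with 3 of 4 guides lower (permutation adjusted p = 0.827). Its guides ranged from 2 reads in proinsulin-high against 30 in proinsulin-low, a share of 6.25% (exact 95% interval 0.766 to 20.8), to 17 against 13. Ins1 had 2 guides past the filter with a median of −0.02, too few for the gene test. In a simulated screen, 33 of 33 genes with an 8-fold shift toward proinsulin-low were called with the counts kept apart. After the counts were joined and read the same way, only 15 of them stayed testable and 7 were called. Strong losses of signal were thus poorly measured. Among beta cell transcription factors, Isl1 (1.36, 3 of 3 guides) and Ldb1 (1.27, 4 of 4) lay on the high side and Nkx2-2 (−1.01, 3 of 3) on the low side. None of these 3 was called over all genes, and all 3 passed when adjusted over the list alone. Nkx6-1 had 0.56, Mafa 0.30 and Neurod1 −0.73, the last 2 genes with 2 guides each, and Pdx1 had no guide past the filter. The stress sensors Ern1 and Eif2ak3 had −0.44 and 0.11, and the transcription factor Xbp1 had 0.36. Of the disulfide-forming enzymes, P4hb had 0.68 with 5 of 5 guides higher (permutation adjusted p = 0.652), Pdia6 −1.08 with 3 of 3 lower (permutation adjusted p = 0.672), Prdx4 0.35, Qsox1 0.00 and Qsox2 0.14. The chaperone Hspa5 had 1 guide past the filter, at 0.73.

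Gene lists were compared next, each by its median gene log2 ratio and the percentile of that median among 10000 random lists matched on guide counts, as a description of these libraries. Of 19 lists, 4 lay above the random 95% range, 3 below it and 12 within it. Cytosolic ribosomal proteins had a median of 0.32 (percentile 100, 21 of 30 genes above 0), with only 30 of the list's 76 genes left to test after the count filter. None was called over all genes, and Rpl24 (1.23) and Rpl23a (1.01) passed when adjusted over the list alone. ER translocation and signal peptide cleavage had 0.27 (percentile 100, 17 of 28 genes above 0), with the signal recognition particle proteins Srp9 (1.56) and Srp14 (0.93), its receptor subunit Srpr (0.96) and Tram1 (0.80) past the threshold when adjusted over the list alone and none over all genes. Emc10 was its lowest member at −0.64. This list's percentile was 96.5 with a 32-fold reading limit and 97.45 with settled strings alone, and its median was −0.16 with a count filter of 100.

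Genes of the unfolded protein response had a median of 0.21 (percentile 99.15, 14 of 20 above 0), from Creb3l2 at −0.51 to Ppp1r15b at 0.53, and none passed the gene test, over all genes or adjusted over the list alone. That list returned to the random range with a count filter of 10 (percentile 90.4) and with guide means (92.2). Granule formation and post-Golgi sorting genes had 0.14 (percentile 98.8, 25 of 39 above 0). Hid1 was called over all genes, and the GARP subunit Vps54 (1.14) and the SNARE Vti1a (0.79) passed when adjusted over the list alone. Its lowest member was Tbc1d5 at −1.16, and its percentile was 84.6 with settled strings alone.

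ER-associated degradation genes had a median of −0.32 (percentile 0.01), with 17 of 24 genes below 0. They ran from the ubiquitin ligase Syvn1 at −0.92 to the lectin Erlec1 at 0.44, its partner Sel1l had −0.43, and no member passed the gene test, over all genes or adjusted over the list alone. ER to Golgi transport genes had −0.15 (percentile 0.37), with 31 of 47 genes below 0. Sec22b, Sec24c and Yipf5 were called over all genes, and adjusted over the list alone 7 genes passed toward proinsulin-low, adding Sec13, Sec24d (−0.84), Surf4 (−1.40) and Use1 (−1.07). Gorasp1, a Golgi stacking protein, passed in the other direction when adjusted over the list alone (1.02). This list's percentile was 13.4 with settled strings alone, and its median was 0.092 with a count filter of 100.

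Mitochondrial respiratory chain genes had a median of −0.18 (percentile 0.02), with 53 of 73 genes below 0. None was called over all genes, and Cox5b (−1.38), Uqcrc1 (−1.08), Cox6b1 (−1.07) and Ndufv1 (−0.18) passed when adjusted over the list alone. Ndufs1 was the highest member at 0.52, and with a count filter of 100 the list median was 0.051.

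**Figure D2:**
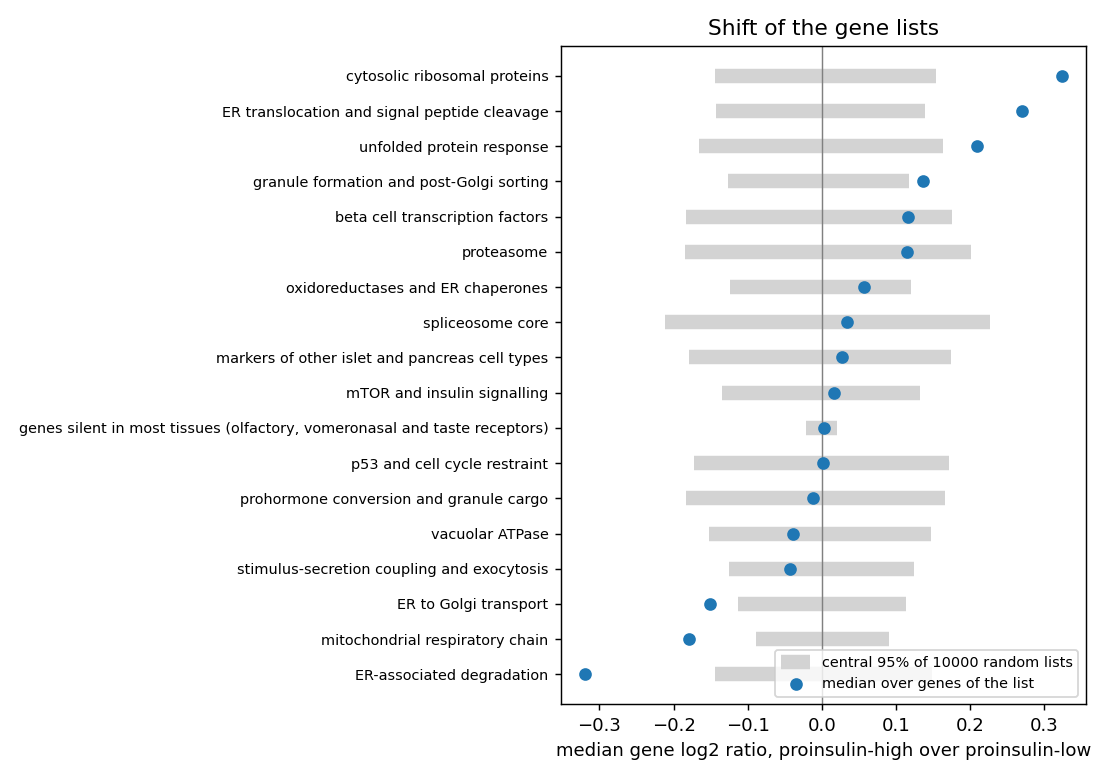
Points are the medians over the genes of each list of the log2 ratio (proinsulin-high over proinsulin-low), and grey bars span the central 95% of 10000 random lists matched on guide counts, for lists with at least 3 genes tested. Ribosomal proteins lie at 0.32 and ER-associated degradation at −0.32, both outside their bars.

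The other lists lay within the random range. Prohormone conversion and granule cargo had a median of −0.01 (percentile 47.6), with Pcsk1 called and Cpe added when adjusted over the list alone. Beta cell transcription factors had 0.12 (90.04), and oxidoreductases and ER chaperones 0.057 (82.1), with Manf low when adjusted over the list alone. The proteasome had 0.11 (87.4), from Psmd2 at −0.61 to Psmb1 at 0.74. Under a count filter of 100 its median was −0.60 (percentile 0.85), over the fewer genes which that filter left, 3523 of 19416 in all. Stimulus-secretion coupling and exocytosis had −0.042 (24.4), from Rims2 at −0.69 to the granuphilin gene Sytl4 at 1.33, and Sytl4 and the channel subunit Abcc8 (1.04) passed when adjusted over the list alone. The mTOR and insulin signalling list had 0.016 (59.0), from Rptor at −0.99 to Depdc5, with Lamtor1 (0.84) joining Depdc5 when adjusted over the list alone. The vacuolar ATPase had −0.039 (31.3), from Atp6v0a1 at −0.94 to Atp6ap1 at 0.45. Core spliceosome genes had 0.034 (59.6), from Snrnp70 at −0.76 to Snrpd1 at 0.44, and p53 and cell cycle restraint genes had 0.0010 (49.5), from Chek2 at −0.32 to Mdm2 at 0.36. Of the insulin genes, Ins2 alone was tested (14.6), and it passed when adjusted over the list alone, a list of 1 gene. Markers of other islet and pancreas cells had 0.028 (61.8), from Hhex at −0.60 to Ptf1a at 0.48.

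Receptor genes silent in most tissues served as a background and had a median of 0.0027 (percentile 59.6) over 1372 genes, from Olfr1022 at −1.51 to Olfr418-ps1 at 1.11, with 1 call, Olfr1475. Non-targeting guides had a robust SD of 0.43 in log2 ratio, against 0.54 for all guides and a median counting error of 0.34. Of the guides against genes, 4.68% lay more than 2-fold toward proinsulin-high, against 2.18% of non-targeting guides. Mock genes made from non-targeting guides gave 0 calls among 275, with 9 and 3 at an unadjusted p under 0.05 toward high and low and 13.75 expected in each direction by chance. Over all genes, 1052 (5.42%) and 1020 (5.25%) had an unadjusted p under 0.05. Guides of the same gene had a correlation of 0.0377 (Pearson) and 0.0284 (Spearman) over 152760 pairs across genes, which are not independent replicates, and the highest Pearson value in 1000 shuffles of gene labels was 0.00999 (permutation p = 0.000999, the smallest they can give).

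Guides against genes that dividing cells need were scarce in both libraries. Summed over both, the median guide had 26.25 reads for ribosomal proteins, 34.25 for the proteasome, 28 for the core spliceosome and 43.5 for the respiratory chain, against 66 for non-targeting guides and 57.5 for silent receptors. The ribosomal value was 0.398 of the non-targeting one, and 0.538 in proinsulin-high alone against 0.346 in proinsulin-low alone. The same ratios were 0.557 against 0.436 for the proteasome, 0.491 against 0.397 for the spliceosome and, the other way, 0.604 against 0.705 for the respiratory chain. All 4 lists lay below every 1 of 10000 random lists of genes in the summed counts, but no unsorted or starting library was analysed here, so loss during culture was not measured. The Gini indices of reads over guides were 0.467 in proinsulin-high and 0.471 in proinsulin-low, and across 90350 guides the log2 reads of the libraries had a Pearson r of 0.774 (Spearman 0.784).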

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

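Guides absent from the proinsulin-high library carried no gene name and entered no gene comparison, and 3 of these 2561 guides had 30 or more reads in the proinsulin-low library. Their counts were 41, 34 and 30 reads, above the 3 reads that a count of 0 allows, while the median guide of this kind had 3 reads. The genes they target were not named here.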

How the results depend on the processing

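No paired analysis was possible because there was 1 library per population. The alternatives on the reading of strings and on at least 4 guides for the gene test were chosen after seeing the data, and leaving out sequences listed under more than 1 gene was not run, since sequences were not used here. The cause was not tested except where fewer genes could be tested. Other pseudocounts, total scaling, non-targeting centring and leaving out NA guides kept 18 and 6 calls, but scaling and centring add a constant and cannot change ranks. Calls toward high and low were 4 and 1 with a count filter of 100 (3523 genes tested), 11 and 3 without the most extreme guide, 115 and 35 with ranks among non-targeting guides, 0 and 3 in library part A, 1 and 1 in part B (6980 and 7704 genes tested), 63 and 24 at an adjusted p of 0.25, 9 and 1 with settled strings alone, and 11 and 3 with a 32-fold limit, many of the calls lost being of genes left with too few guides to test. Toward low they were 3 with 4 guides per gene and 1 with the least favourable reading. Part A kept 0 of the 18 main high calls and 2 of the 6 low ones, with 12 and 4 not testable there. Part B kept 1 and 0, with 11 and 4 not testable, so several calls that could be tested were lost in a part as well. Raw ratio ranks kept 10 of 18 high calls and 5 of 6 low calls, and medians of z scores kept 12 and 4. A count filter of 10 lost Eprs, Olfr1475, Smc3 and Slc35b1, and no filter lost Dkc1, Olfr1475, Smc3, Slc35b1 and Sumo2, all still tested. With a count filter of 100, list medians were −0.16 for ER translocation, 0.12 for the unfolded protein response, −0.29 for ER-associated degradation, 0.092 for ER to Golgi transport, 0.13 for granule formation, 0.26 for mTOR signalling, −0.60 for the proteasome and 0.051 for the respiratory chain. These medians cover only the list genes still tested at that filter, whose numbers are not given here. The unfolded protein response had 0.11 with a filter of 10 and 0.10 with guide means, where insulin genes had −0.68 and oxidoreductases 0.11. With settled strings alone ER translocation had 0.15, ER to Golgi transport −0.073 and granule formation 0.060, and with a 32-fold limit ER translocation had 0.13. The other 171 list values kept their direction and side of the random range or stayed within it. Gini indices over guides past the filter were 0.355 and 0.352. Olfr1475 had −0.12 with a filter of 10, −0.12 in part B, −0.16 with settled strings and −0.13 with a 32-fold limit, and Fmo2 had 0.087 with a filter of 100, 0.072 in part B and 0.057 with a 32-fold limit. Depth was a limit, as 22.8% and 16.8% of guides had under 10 reads in proinsulin-high and proinsulin-low.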

Other observations

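Several top genes belonged to complexes that had no fixed list of their own, and 7 such groups were drawn up after the top genes had been seen and tested on their other members. Only these 7 were tested. A group was taken to lie on a side as a whole if those other members passed the random 95% range, as was set before their values were looked at, except for Ragulator and GATOR1, where some members had been scored in a fixed list. Ribosome assembly factors beyond those among the top genes had a median log2 ratio of 0.45 over 80 genes (percentile 100), 68 of them above 0, from Pwp2 at −1.04 to Sbds at 1.43. Cohesin and its regulators, among which Smc3 was called, had 0.59 over 9 others (percentile 100), 8 above 0, with Wapal at 1.23 and Esco1 at −0.41. Ragulator, GATOR1 and partners that act with them on mTORC1, such as the Rag GTPases and folliculin, had 0.31 over 9 others (percentile 99.3), with Lamtor4 at 0.72 and Flcn at −0.86. Of these, 4 belonged to the fixed mTOR list, and the 5 outside it had a median of −0.24 (percentile 7.45), so this group's side stays open. N-glycan assembly and transfer genes, the pathway of Dpagt1, had 0.20 over 30 others (percentile 99.8), with Alg11 highest at 0.87.

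On the other side, mitochondrial ribosome proteins had a median of −0.27 over 68 genes (percentile 0), with 56 below 0 and Mrpl36 lowest at −1.03. Members of the SAGA histone acetylation complex, beyond Ccdc101, Taf5l and Atxn7l3, had −0.22 over 14 genes (percentile 1.24), 12 of them below 0, with Taf6l lowest at −0.75 and Usp22 highest at 0.38. Subunits of the BLOC-1 and BORC complexes had 0.14 over 8 others (percentile 89.8), within the random range, which leaves open whether the group lies on that side. With settled strings alone, an alternative chosen after the data were seen, the percentiles were 100 for ribosome assembly, 100 for cohesin, 99.8 for Ragulator and GATOR1, 99.0 for N-glycans, 0 for mitochondrial ribosomes, 0.43 for SAGA and 89.8 for BLOC-1 and BORC. One hypothesis is that loss of ribosome assembly, cohesin or N-glycan assembly may raise proinsulin staining per cell, and loss of mitochondrial translation or SAGA may lower it. Whether loss of guides from the culture moved these groups was not tested. A second sort would be needed, as the groups were found in the same libraries.

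For the patterns below, the tests of misread strings, of loss from the culture and of the high readings of unread strings were chosen after the values they use had been seen. ER to Golgi transport genes lay toward proinsulin-low. An effect of 1 part of the guide library alone stays open. The percentile of the list was 0.19 in part B but 5.66 in part A, within the random range. Misreading of joined counts stays open, because the percentile was 0.97 with a 32-fold limit but 13.4 with settled strings alone, a setting that also drops many unequal counts by construction. The sorted populations differ by design in proinsulin staining, and that explanation was not tested apart from reading errors.

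Ribosomal protein genes lay toward proinsulin-high and respiratory chain genes toward proinsulin-low. Loss of guides from the culture stays open, since the other lists with few reads, the proteasome and the spliceosome, had percentiles of 87.4 and 59.6, within the random range. Only 30 of 76 ribosomal, 19 of 32 proteasome and 14 of 23 spliceosome genes kept enough guides to be tested. Over all guides read, the ratio to non-targeting guides was higher in proinsulin-high than in proinsulin-low for ribosomal proteins (0.538 against 0.346). The same held for the proteasome (0.557 against 0.436) and the spliceosome (0.491 against 0.397). For the respiratory chain it was lower (0.604 against 0.705). The proteasome median was −0.60 with a count filter of 100, which left 3523 of 19416 genes. The median proteasome guide had 34.25 reads over both libraries. How many proteasome genes passed that filter is not given here, so this value settles nothing. Misread strings were argued against, with percentiles of 99.97 and 0 from settled strings alone. One part of the library as the sole source was argued against for the respiratory chain, with percentiles of 0.03 in part A and 0 in part B. For ribosomal proteins it stays open, with 99.16 in part B but 94.75 in part A, within the random 95% range. The ribosomal values met only a looser mark set beforehand. No biological explanation was tested, and with a count filter of 100 the respiratory median was 0.051.

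Unread strings seemed to gather in Pcsk1 and Cpe, with 2 each. Over 21788 genes, 0 had more unread strings than chance at an adjusted binomial p under 0.05 (lowest adjusted p = 0.956). Cpe and Pcsk1 had unadjusted binomial p of 0.00062 and 0.00092. A gene with 2 unread strings cannot pass over that many genes, so the test could not single them out. In all, 21 genes had 2 unread strings where 17.5 were expected, which leaves random placement possible. In the simulation, 14.6% of guides against changed genes were unread, against 0.42% of all guides. All 4 unread strings of these genes had a possible reading beyond 4-fold toward proinsulin-high and 0 settled guides lay beyond 2-fold toward proinsulin-low. These strings also had readings toward proinsulin-low, which keeps the question of strong ratios open. Unread strings of Pdia6 and Ins1 had a reading beyond 4-fold toward proinsulin-high as well, while that of Sytl4 did not. Such a reading is thus not particular to Pcsk1 and Cpe.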
